A study of Mus musculus with 4 samples.

How the data were processed

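RNA-seq was analysed for 4 libraries of mouse bone marrow leukaemia cells, 2 WT and 2 Ybx1 cKO. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was isolated with oligo dT beads, and libraries were made with a VAHTS mRNA-seq V2 kit after fragmentation and random priming. Whether the kit or the counting used strand was not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. Per the submitters' processing notes, CASAVA, HISAT2 2.1.0, featureCounts and DESeq2 were used on GRCm38, with no role or order given.

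The table holds, for 28141 gene symbols, 1 deposited score per gene and library, from -3.19 to 27.9. These values were on a log scale of unstated base, and which transformation the authors applied, and on which libraries, was not given in the sources used here. Column names matched the samples by title, and 0 columns of values were left out. The scale was inferred from the values. In bins of 1 unit from 5 to 16, the SD of the difference between replicates (from the median absolute deviation) was compared with Poisson noise. The Poisson noise was computed as if the back-transformed level were a number of reads, which is an assumption. If the scores are log2 levels multiplied by 1.44, which is 1/ln(2), the median ratio of observed to Poisson SD was 1.11 in WT and 1.33 in cKO; if they are plain log2, it was 5.27 and 6.18, and if natural logarithms, 41.5 and 48.5. The slope of the noise on the level, which does not use the size of the noise, gave 1.62 units per doubling in WT and 1.57 in cKO. All scores were therefore multiplied by 0.693. Summed after this step and back-transformed, the levels came to 11157952 and 11074317 in the WT libraries and 12104617 and 12134026 in the cKO libraries. As these are not known to be counts, depth is unknown, and no interval from counting is given. Replicates differed by little more than sampling noise on this reading, which was itself chosen partly for that closeness. In the lowest bins the observed noise stayed below the Poisson noise of this reading, and whether changes of low genes are understated was not tested.

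The comparison had been planned for counts, with normalized values as a fallback. Because the unit differed from the planned one, the fallback was used without its pseudocount, as the scores are already logarithmic. Genes with a score of at least 1 in at least 2 libraries were tested, 15527 in all, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are cKO minus WT, and SEs come from the moderated variance. Levels per 1000000 are back-transformed levels over the library sum. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.

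Before the data were examined, 31 gene lists were fixed, covering the Y-box family, 14-3-3 proteins, m6A factors, apoptosis, p53, the cell cycle, stem cells, signalling, ribosomes, metabolism, stress, interferon and inflammation, the marrow cell types, mitochondrial transcripts and sex-linked genes. Of 741 distinct listed genes, 602 had a row in the table used here. The sex-linked list served as a check and was not tested: its 4 Y-linked genes had no row. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, adjusted over these lists; camera with an estimated correlation and fry were alternatives. With 4 libraries and 2 group means, an estimated correlation rests on 2 residual degrees of freedom. Camera then also refers its statistic to these 2 degrees of freedom, so a call can be lost without a higher correlation. Among called lists the estimate lay below 0.01 for some, such as S phase (0.001) and interferon (-0.033). It lay above 0.01 for others, such as ribosomal proteins (0.078), mitosis (0.18) and mitochondrial transcripts (0.53).

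Named genes followed a rule fixed at the same time: Ybx1, Ybx2, Ybx3, Ywhaz, Bcl2, Myc, Kit and Cd34 in any case; the 12 largest rises and 12 largest falls among called genes at a mean level of 5 or more per 1000000 whose groups did not overlap, leaving out predicted models and antigen receptor segments; and up to 4 called members with the smallest p-values of each list, or up to 2 members given as values where none passed. Some single genes are not reported here. Gene positions come from GENCODE M21 on GRCm38, in which 27216 of the symbols were found.

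The test was checked on simulated values for the real genes, with the noise seen between replicates at each level and some genes changed by known amounts, of which 49 each at 1.25-fold and 1.5-fold and 50 each at 2-fold and 4-fold entered the test. In the simulation of Ybx1 cKO against WT, run on 15590 genes, 38.8% of genes changed 1.25-fold were recovered, 51.0% at 1.5-fold, 60.0% at 2-fold and 92.0% at 4-fold, and 6.98% of the calls were false. Of 30 simulated lists, 3 were shifted and all 3 were called, with 0 false calls. The simulated noise was independent between genes, so these lists held no correlation. Their false calls therefore say nothing about lists whose genes vary together. Far fewer genes were changed in the simulation than were called in the data. Simulated genes at the same level also shared 1 normal noise SD, which is close to what the mean-variance trend assumes. The recovery and false-call rates therefore do not test that assumption. Alternatives were other filters, other thresholds, a replicate block, leaving out each library, and, chosen after the data were seen, quantile normalization, a median shift, other prior variances and no rescaling. Tests that need counts or linear values, and a comparison with the authors' own calls, were not run.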

Results

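The libraries held polyadenylated RNA of leukaemia cells collected from the bone marrow of C57BL/6 mice, which the labels call LSCs without spelling the name out. There were 2 groups of 2 libraries each, 1 from wild-type cells (WT) and 1 from cells with a conditional knockout of Ybx1 (Ybx1 cKO). Ybx1 encodes a Y-box protein that binds RNA and DNA. The table held 28141 genes with 1 value on a log scale per gene and library, and 15527 of them entered the test. Depth was unknown because the table held no counts. Levels and fold changes are given on a log2 scale obtained by multiplying the deposited values by 0.693, a factor inferred from the noise between replicates and not stated in the sources. If the deposited values were plain log2, every log2 fold change given here would be 1.44 times as large, while the p-values would stay as they are. Nothing in the labels said that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. For each gene that spread was moderated towards the spread of genes at a similar level.

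**Figure D1:**
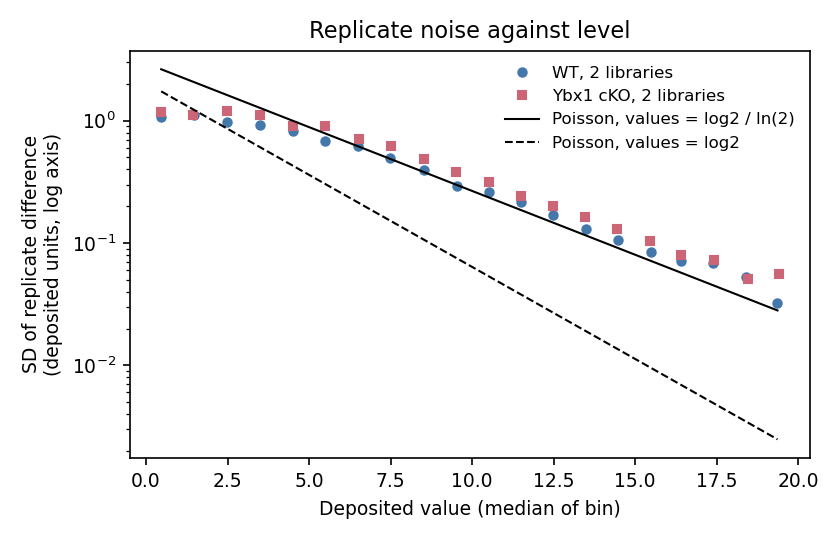
SD of the difference between the 2 replicates of a group (deposited units, log axis) against the median deposited value of the genes in each bin, for WT (circles) and Ybx1 cKO (squares). The solid line is Poisson sampling noise if the values are log2 levels divided by ln(2), and the dashed line is the same if they are log2 levels; the median ratio of observed noise to the solid line was 1.11 in WT and 1.33 in cKO, and to the dashed line 5.27 and 6.18.

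Ybx1 was lower in both cKO libraries than in both WT libraries. Its log2 level was 9.36 ± 0.07 (SD, n = 2) in WT and 8.16 ± 0.04 (SD, n = 2) in cKO, a 2.29-fold fall (log2 fold change -1.20, SE 0.08, limma adjusted p = 1.1e-11). The single libraries stood at 9.31 and 9.41 in WT and at 8.19 and 8.13 in cKO. Ybx1 lies on chromosome 4 from 119277981 to 119294604 in GRCm38. A conditional deletion can leave reads from exons outside the deleted part, and the deleted exons were not given in the sources used here. Its relative Ybx3 also fell, by 0.59 on the log2 scale (SE 0.19, limma adjusted p = 0.014), but without WT replicate 1 that call was lost (adjusted p = 0.14). Ybx2 lay below the level needed for the test, with a log2 level of 0.24 ± 0.48 (SD, n = 2) in WT and 0.60 ± 0.26 (SD, n = 2) in cKO.

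**Figure D2:**
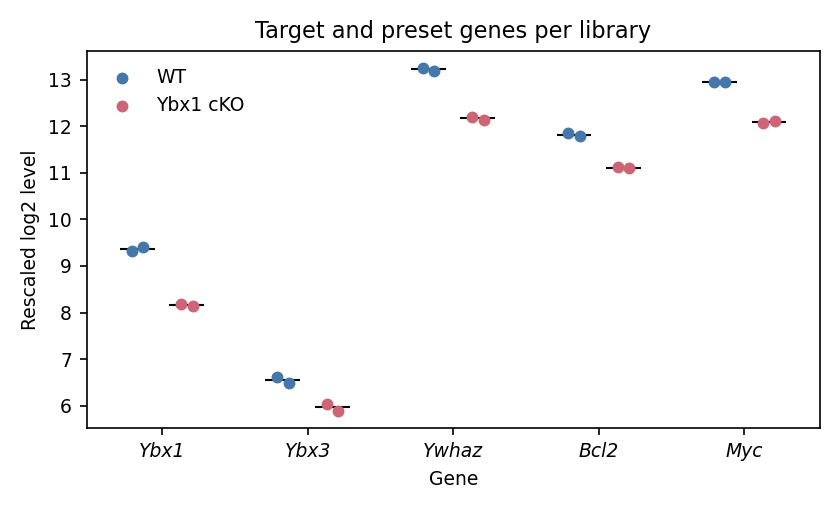
Log2 level (deposited value multiplied by 0.693) of Ybx1, Ybx3, Ywhaz, Bcl2 and Myc in each of the 2 WT and 2 Ybx1 cKO libraries; points are libraries and lines are group means. For each of the 5 genes both cKO libraries lie below both WT libraries, with Ybx1 at 9.31 and 9.41 in WT and at 8.19 and 8.13 in cKO.

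The comparison of the 2 genotypes asked which transcripts depend on Ybx1 in these cells. The largest rises included Mmp8 from the neutrophil list, Lyz2 from the monocyte list and Ppbp from the platelet list, and the largest falls included Irf7 and Rtp4 from the interferon list, Anln from the mitosis list and Pola1 from the S phase list. Of the 12 largest rises among genes at 5 or more per 1000000 of the library sum, Cstdc5 rose 8.87-fold, Mmp27 8.48-fold, Hsd11b1 8.30-fold, Stfa1 7.94-fold, Wfdc18 7.65-fold, Mmp8 6.72-fold and Arg1 6.27-fold. Mmp8 is neutrophil collagenase, and Arg1 is the arginase of alternatively activated myeloid cells. The other 5 were Klra2, Tnfrsf26, Lyz2, Stfa2 and Ppbp, with rises from 4.29-fold for Ppbp to 5.96-fold for Klra2. Among the 12 largest falls, the chemokine gene Ccl5 fell 9.05-fold, Irf7, a main regulator of interferon genes, 5.82-fold, the centriole gene Ccp110 5.09-fold and Iqgap3 4.60-fold. Apol9b, Apol9a, Rtp4, Pola1, Anln, Podnl1, Itgb3 and Pomp fell between 4.57-fold for Apol9b and 3.71-fold for Pomp. The largest adjusted p among these 24 genes was 5.5e-08 (limma), for Iqgap3. Stfa1, Stfa2 and Cstdc5 belong to a cluster of near-identical stefin genes and Apol9a and Apol9b are near-identical copies, so reads could be split between them.

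Together 5803 of the 15527 genes tested (37.4%) changed at a limma adjusted p under 0.05, of which 3035 were higher and 2768 lower in cKO. It stayed open whether genes seen only in cKO got a row less often, as described in the last part. The rises, the largest ones included, may therefore be undercounted. At least a 2-fold change was seen for 372 genes that rose and 482 that fell, and at least a 4-fold change for 27 and 20. Without letting the prior variance follow the level, which was tried after the data were seen, the total was 2267 genes. Both cKO libraries lay on one side of both WT libraries for 65.1% of the tested genes, where chance gives 33.3%.

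Genes of the cell cycle fell together in cKO. All 30 genes of the G2/M and mitosis list fell, with a median log2 fold change of -1.27. Among them the log2 fold change was -1.48 (SE 0.05) for Top2a, the DNA topoisomerase of dividing cells, -1.30 (SE 0.05) for the mitotic cyclin gene Ccnb1, -1.12 (SE 0.06) for the mitotic kinase gene Plk1 and -0.95 (SE 0.05) for Cdc20. Of the 32 S phase and DNA replication genes, 29 fell, 2 rose and 1, Pole, did not pass (log2 fold change -0.41, adjusted p = 0.070). The ribonucleotide reductase gene Rrm2 had a log2 fold change of -1.44 (SE 0.04), and the replicative helicase genes Mcm3 and Mcm2 had -1.15 (SE 0.05) and -1.04 (SE 0.04). Adjusted over the list alone, 30 of the mitosis genes and 30 of the S phase genes fell. By camera with a preset correlation the mitosis list had an adjusted p of 1.3e-28 and the S phase list 3.3e-22. Both calls were lost when camera estimated the correlation, with adjusted p = 0.21 and adjusted p = 0.11. That estimate was 0.18 for mitosis and 0.001 for S phase, so the S phase call was not lost through a correlation above the preset one.

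Interferon response genes were lower in cKO. Of 29 tested genes of the type I interferon list, 27 fell and Ifit2 rose (log2 fold change 0.71, SE 0.06), with a list median of -0.86; adjusted over the list alone, 28 fell and 1 rose. The antiviral genes Oasl1, Oas3 and Ifit1 had log2 fold changes of -1.77 (SE 0.06), -1.38 (SE 0.05) and -1.32 (SE 0.05). The camera adjusted p was 5.2e-20, but adjusted p = 0.11 with an estimated correlation. Of 18 NF-kB and inflammatory genes, 11 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.39, camera adjusted p = 3.5e-04, and adjusted p = 0.21 with an estimated correlation). The log2 fold change was -1.39 (SE 0.16) for the cytokine gene Il6, -0.91 (SE 0.04) for the chemokine gene Ccl3, -0.69 (SE 0.03) for the lectin gene Clec4e and -0.67 (SE 0.04) for Nfkb2. Nfkb1, Il1rn and Cxcl2 were the 3 that rose, and are named here after their values were seen.

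Genes for ribosomes and their assembly fell by smaller amounts. Of the 35 ribosome biogenesis genes linked to MYC, 29 fell and 0 rose, also when adjusted over the list alone, with a median of -0.43. The log2 fold change was -0.87 (SE 0.04) for Pa2g4, and for the nucleolar genes it was -0.80 (SE 0.03) for Npm1, -0.74 (SE 0.03) for Nop56 and -0.59 (SE 0.03) for Ncl. Of 79 cytosolic ribosomal protein genes, 59 fell and 3 rose (62 and 3 adjusted over the list alone; median -0.31). Rplp0, Rps4x and Rpl13 had log2 fold changes of -0.55 (SE 0.02), -0.53 (SE 0.04) and -0.42 (SE 0.03), while Rps25 rose by 0.47 (SE 0.03). The camera adjusted p was 1.7e-14 for ribosome biogenesis and 2.5e-16 for the ribosomal proteins. With an estimated correlation neither call held (adjusted p = 0.11 and adjusted p = 0.21).

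Myc itself fell 1.81-fold in cKO (log2 fold change -0.86, SE 0.03), from a log2 level of 12.95 to 12.09. Bcl2, which protects cells from apoptosis, fell 1.63-fold (log2 fold change -0.71, SE 0.04), and Ywhaz, which encodes the 14-3-3 protein zeta, fell 2.08-fold (log2 fold change -1.05, SE 0.03). Of the other 14-3-3 genes, Ywhab rose by 0.42 on the log2 scale (SE 0.03), Ywhaq by 0.26 (SE 0.03) and Ywhae by 0.27 (SE 0.02), although Ywhae lost its call under quantile normalization (log2 fold change 0.01). Of the 7 genes of this list 4 rose and 1 fell, also adjusted over the list alone, and the list had a median of 0.20 (0.01 under quantile normalization), a mean of -0.02 and no call (camera adjusted p = 0.23). Of 14 anti-apoptotic genes 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.93). Birc5, which also serves mitosis, had a log2 fold change of -1.20 (SE 0.08), whereas Cflar rose by 0.62 (SE 0.06) and Bcl2l1 by 0.35 (SE 0.03). Of 21 pro-apoptotic genes 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.93). Kit and Cd34, which were to be named in any case, had no row in the table used here.

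Genes of mature neutrophils and some of monocytes were higher in cKO. Of the 24 mature neutrophil genes listed, 11 had a row, of which 10 rose and 1, Padi4, fell (log2 fold change -0.17, SE 0.06), also when adjusted over the list alone; the median was 1.44. Mmp8 rose by 2.75 on the log2 scale (SE 0.05), Stfa2l1 by 1.80 (SE 0.12), the gelatinase gene Mmp9 by 1.67 (SE 0.03) and Ceacam1 by 0.94 (SE 0.06). The camera adjusted p was 1.5e-07, but adjusted p = 0.21 with an estimated correlation. Of 13 tested monocyte and macrophage markers 5 rose and 3 fell, also adjusted over the list alone, and the lowest log2 fold change was -1.57. The lysozyme gene Lyz2 rose by 2.25 on the log2 scale (SE 0.02), the endotoxin co-receptor gene Cd14 by 1.17 (SE 0.05), Cd68 by 0.77 (SE 0.03) and Ccr2 by 0.63 (SE 0.06). That list had a camera adjusted p of 0.017, which was lost with an estimated correlation (adjusted p = 0.32) and under quantile normalization (adjusted p = 0.24). Of 10 tested genes of granulocyte progenitors and primary granules 4 rose and 2 fell, also adjusted over the list alone, with Igsf6 up by 1.58 (SE 0.07) and the granulocyte regulator gene Cebpe among the rises, and no call for the list (camera adjusted p = 0.34).

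Transcripts of the mitochondrial genome were higher in cKO. Of 11 tested genes 9 rose and 0 fell, also adjusted over the list alone, with a median of 0.61. mt-Nd5 rose by 0.76 on the log2 scale (SE 0.05), mt-Nd4 by 0.63 (SE 0.06), mt-Co1 by 0.61 (SE 0.03) and mt-Cytb by 0.43 (SE 0.02). The camera adjusted p was 4.1e-06, and adjusted p = 0.50 with an estimated correlation. The 40 nuclear genes of oxidative phosphorylation went both ways, with 15 rises and 9 falls (15 and 10 adjusted over the list alone; camera adjusted p = 0.53). Of 20 glycolysis genes 5 rose and 9 fell (5 and 10 adjusted over the list alone; median -0.23, camera adjusted p = 0.063). Tpi1, Ldha and Eno1 had log2 fold changes of -0.56 (SE 0.03), -0.41 (SE 0.02) and -0.33 (SE 0.02).

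**Figure D3:**
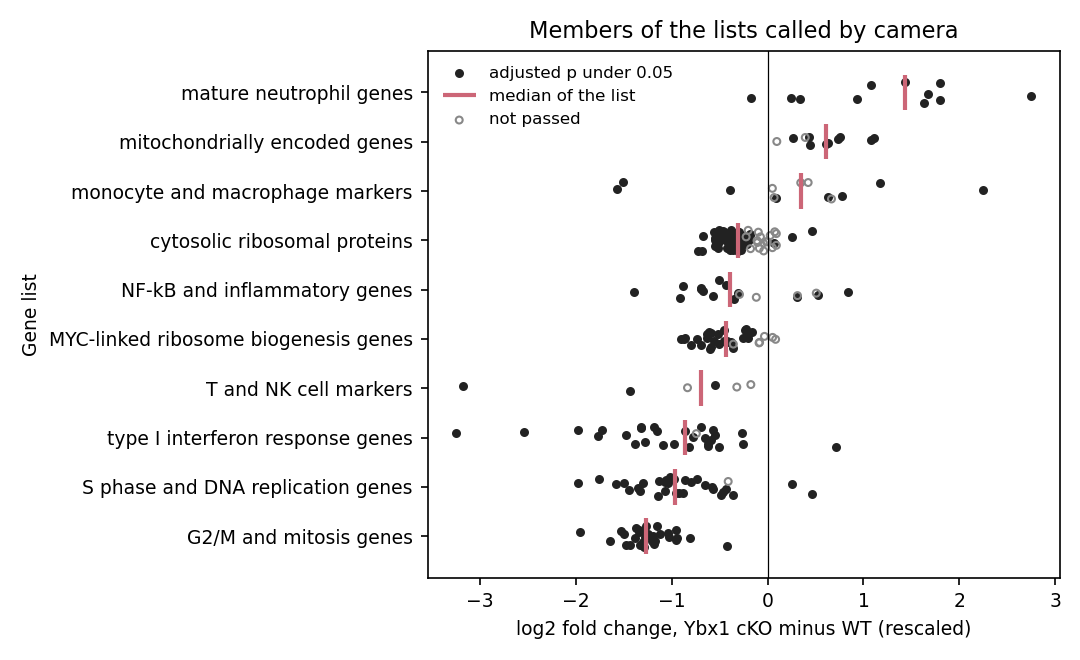
Log2 fold change (Ybx1 cKO minus WT, rescaled values) of each tested member of the 10 lists called by camera with a preset correlation; each point is a gene, filled where its limma adjusted p was under 0.05, and the bar is the median of the list. The 30 mitosis genes all lie below 0 around a median of -1.27, and the mature neutrophil genes lie around a median of 1.44; with an estimated correlation 0 of the 10 lists were called.

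The tested T and NK cell and erythroid markers had falls among them and no rise that passed. Of 6 tested T and NK cell markers 3 fell and 0 rose, also adjusted over the list alone (median -0.69, camera adjusted p = 4.5e-03, and adjusted p = 0.30 with an estimated correlation), and the median ranged from -1.12 without cKO replicate 1 to -0.50 without cKO replicate 2; the 3 were Ccl5, the granzyme gene Gzmb (down by a log2 fold change of -1.44, SE 0.08) and Lat. Of the 24 erythroid markers listed, 17 had no row. Of 7 tested erythroid markers 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.20). That share is near the 37.4% of all tested genes that were called. Hemgn was down by a log2 fold change of -1.31 (SE 0.18), Tfrc by -0.51 (SE 0.07) and Gata1 by -0.22 (SE 0.06). Of the B cell markers 2 were tested and 1, Cd79b, rose, too few for a list test; its call was lost without WT replicate 1 (adjusted p = 0.27), without WT replicate 2 (adjusted p = 0.064) and without cKO replicate 1 (adjusted p = 0.20). Of 18 megakaryocyte and platelet genes 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.55): the chemokine gene Ppbp and the thrombin receptor relative F2rl2 rose 4.29-fold and 2.52-fold, and the integrin gene Itgb3 and F2r fell 3.72-fold and 1.70-fold. Of 11 antigen presentation and dendritic cell markers 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.93), with Cd74 up by 0.85 (SE 0.05). Of 10 basophil, mast cell and eosinophil markers 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.96), and of 14 endothelial and stromal markers 1 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.64).

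Stem cell and signalling genes moved in both directions and their lists were not called. Of 21 tested haematopoietic stem and progenitor genes 3 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.28), among them Mecom, a regulator of stem cell self-renewal, down by a log2 fold change of -0.60 (SE 0.04), Gata2 by -0.43 (SE 0.05) and Mycn up by 0.28 (SE 0.04). Of 18 genes that earlier work linked to stem cells of chronic myeloid leukaemia 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.41): Hif1a, the hypoxia regulator, had a log2 fold change of -1.51 (SE 0.05) and Pml of -1.13 (SE 0.07), and Foxo3 rose by 0.75 (SE 0.07). Without cKO replicate 2 this list was called (adjusted p = 0.038), and so was glycolysis (adjusted p = 0.027). Of 23 JAK-STAT5 and RAS-MAPK output genes 7 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.64), with Il2ra down by a log2 fold change of -0.75 (SE 0.04) and Dusp6 up by 0.47 (SE 0.03). Of 23 p53 targets 1, Cdkn1a, rose and 8 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.10), and Cdkn1a lost its call under quantile normalization (log2 fold change 0.02). Of 24 ATF4 and unfolded protein response genes 8 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 0.28), with Nupr1 up 3.41-fold, Pdia4 up 1.90-fold and Phgdh down 2.08-fold. Of 19 immediate early genes 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.57), with Klf6 up by 0.85 (SE 0.03). Of 19 m6A writers, erasers and readers 3 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.93), and of 4 Y-box and cold-shock genes 1, Carhsp1, rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.28). Under quantile normalization, tried after the data were seen, the p53 list (adjusted p = 0.021), the ATF4 list (adjusted p = 8.1e-03) and the glycolysis list (adjusted p = 1.2e-06) were called lower. Of the 29 lists tested, 11 had a median, a mean and a camera direction that differed in sign, and 0 of these were called. They were the 14-3-3, m6A, pro-apoptotic, chronic myeloid leukaemia, JAK-STAT5 and RAS-MAPK, immediate early, primary granule, antigen presentation, megakaryocyte, basophil and endothelial lists.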

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

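Quantile normalization, the median shift, the 2 other prior variances and the reading of the scores as plain log2 were chosen after the data were seen; the other alternatives were fixed before. The total of 5803 changed genes (3035 higher, 2768 lower) stayed within 1.5 times under other filters, under adjusted p thresholds of 0.01 and 0.10, under both scalings and under a robust prior, between 4497 and 6653. With a prior variance that does not follow the level, 2267 genes were called, 1177 higher and 1090 lower, of which 2080 were among the 5803; of 128 named genes other than Ybx1, 34 lost their call. With a log2 fold change of at least 1, 854 were called (372 higher, 482 lower), and 1692 (790 higher, 902 lower) when the scores were read as plain log2; both counts are smaller by construction. Leaving out 1 library at a time, where the lone library is assumed to vary like the other group, gave 4662 to 5803 genes, 2485 to 2982 higher and 2140 to 2821 lower. The replicate numbers are not known to pair the libraries (correlation of same-numbered deviations 0.013, with 2 pairs only); a replicate block gave 6026 genes (3138 higher, 2888 lower), 10 lists and a Ybx1 log2 fold change of -1.20, and changed no call of a named gene. Ybx1 stayed lower and called under every alternative run, from -1.25 to -1.15 without 1 library and at -1.73 on the plain log2 reading. With a prior variance that does not follow the level, its limma adjusted p was 0.032. Of the 29 lists tested, 10 were called; camera with an estimated correlation called 0 (lowest adjusted p 0.11) and fry, which does not compare a list with other genes, called 18; the count was 10 to 12 without 1 library. The extra lists without 1 library were the chronic myeloid leukaemia list (adjusted p = 0.038) and glycolysis (adjusted p = 0.027) without cKO replicate 2, and the primary granule list without WT replicate 2 (adjusted p = 0.048). Under quantile normalization 5282 of the 5803 genes stayed called in the same direction, and 53 changed sign, of which 25 were called in the opposite direction. Among named genes it turned the log2 fold changes of Aldoa, Hspa8 and Casp6 from 0.29, 0.14 and 0.17 to -0.031, -0.247 and -0.044, with Hspa8 called lower (limma adjusted p = 2.7e-10). A further 3 named genes lost their call, Ywhae and Cdkn1a among them. Aldoa, Hspa8 and Casp6 had WT log2 levels of 14.2, 14.7 and 12.9, so small changes of abundant genes can depend on the scaling. The cause was not tested. Calls of named genes lost without 1 library were those of Ybx3 and Tcf4 (adjusted p = 0.14 and 0.059 without WT replicate 1), Gata1 (0.062 without cKO replicate 2), Wtap (0.16 without WT replicate 1, 0.089 without cKO replicate 1), Cd79b (0.064 to 0.27), Lpl (0.058 to 0.26) and Runx2 (0.097 to 0.23), the last 3 without any of 3 libraries. Not run, because the table holds no counts, linear values or authors' calls, were the count-based tests and their normalizations, the pseudocounts and the authors' own calls. Depth is unknown, so what it limits could not be stated.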

Other observations

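All tests in this part were chosen after the results were seen. Families of genes that share a symbol stem added groups outside the fixed lists. Of 205 stems with at least 8 tested genes, camera with a preset correlation called 23, and with an estimated correlation 0 (lowest adjusted p = 0.79). Of these 23, 7 picked after their values were seen are described, and others, Rab and Vps among them, are not. Annexin genes, whose proteins bind membranes in the presence of calcium, rose for 7 of 10 members and fell for 0 (median 0.48, camera adjusted p = 1.9e-04), led by Anxa1 with a log2 fold change of 1.24 (SE 0.03). Of 28 sorting nexins 14 rose and 1 fell (median 0.23, camera adjusted p = 0.010), as did 6 and 0 of 10 Chmp genes of the ESCRT-III complex (median 0.32, camera adjusted p = 0.013), 10 and 2 of 14 Trappc genes (median 0.31, camera adjusted p = 0.027) and 12 and 1 of 18 Atg genes (median 0.26, camera adjusted p = 0.035). Chmp1b rose by 0.70 (SE 0.06), Trappc4 by 0.55 (SE 0.04) and Atg7 by 0.45 (SE 0.04). Nucleoporin genes fell for 12 of 20 members (median -0.43, camera adjusted p = 1.1e-03), with Nup160 at -1.32 (SE 0.14). The chaperonin genes with the stem Cct fell for 5 of 8 (median -0.20, and -0.34 under quantile normalization, camera adjusted p = 0.011), with Cct5 at -0.39 (SE 0.03). The 7 families described kept their direction and their call under quantile normalization and under the median shift. Of the called families not described, some lost their call. These were Psmd (camera adjusted p = 0.32) and Irf (camera adjusted p = 0.057) under quantile normalization and Ddx (camera adjusted p = 0.057) under the median shift.

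Among the genes with the highest levels in WT were Spp1 at rank 1, Fth1 at rank 4 and Adgre1, the gene of the macrophage antigen F4/80, at rank 7. These ranks were not corrected for gene length. Predicted gene models picked as repeat-like after their values were seen were Gm10800, Gm10801, Gm10715, Gm10717, Gm10718, Gm10719, Gm10720, Gm10721, Gm10722, Gm21738, Gm11168 and Gm17535. All 12 were lower in cKO, from -0.73 for Gm10801 to -3.38 for Gm10720, and Gm10800 was the gene at rank 2 in WT. Repeat-like models may share reads, so the 12 may not be independent, and the cause of their fall was not tested.

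The first pattern is that cell cycle genes fell while neutrophil genes rose in cKO, which a difference in scaling does not account for, since after quantile normalization the median of the mitosis genes was still -1.22 and that of the neutrophil genes 1.43. A lower share of leukaemia cells would raise the markers of every other cell type alike, but the neutrophil median lay 2.13 log2 units above that of the 6 T and NK cell markers, with a spread of 0.66, and 2.03 to 2.36 above it without 1 library. A margin of 1 log2 unit, written first, was not cleared, since less 2 spreads the distance was 0.82. The criterion used here, a distance from 0 of more than 2 spreads, replaced it after that result was seen. The spread is over the genes of the lists and not over animals. Of the 24 T and NK cell markers listed, 18 had no row, and which cells expressed the 6 tested was not known. This evidence is therefore weak and cannot decide on a lower share of leukaemia cells. More mature neutrophils among the cKO cells could not be told apart from a change within the leukaemia cells: 10 of 11 tested neutrophil genes rose, and 13 of the 24 listed, the most abundant S100a8 and S100a9 among them, had no row in the table used here. An effect of Ybx1 loss on division and maturation of the leukaemia cells stays open as the biological explanation and was not tested.

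The second pattern is the high level of Adgre1 (log2 level 15.82 in WT) and the rise of Lyz2 by 2.25 in cKO. A minority of macrophages mixed into the leukaemia cells would bring their other abundant transcripts, and the evidence on these went both ways: in WT Lyz2 lay 4.62-fold below Adgre1, Cd68 21.2-fold, Ctss 49.9-fold, Mpeg1 66.2-fold and Csf1r 1682-fold, while Spp1, Ftl1 and Fth1, which other cells also express, lay above it. The median of the 12 other tested macrophage markers lay 8.13 log2 units below Adgre1. That was past a margin of 4 by more than 2 spreads of 1.52. Among the 7 markers at 5 or more per 1000000, a restriction added after that result was seen, the distance was 6.05. Less 2 spreads it was 3.93, short of the margin. This restriction removes the markers with the lowest levels and so shortens the distance by construction. No correction for gene length was made here, and whether the scores hold one was not given in the sources used here. The folds and distances between different genes may therefore partly reflect length. For this reason, and because the 12 include markers at low levels, neither distance decides, and macrophages stay open for the level of Adgre1. The other 12 tested monocyte and macrophage markers did not rise with Lyz2 as a set. Their median log2 fold change was 0.22, with a spread of 0.31 over these genes. For the 7 at 5 or more per 1000000 the values were 0.35 and 0.25. Cd14, Cd68 and Ccr2 rose by 1.17, 0.77 and 0.63. Adgre1, Csf1r and Ctss had 0.09, 0.07 and 0.05, Mpeg1 had -0.39, and the lowest of the list was -1.57. More macrophages among the cKO cells cannot be excluded by this for the rise of Lyz2. Markers that the leukaemia cells already make would rise less with added macrophages. No biological explanation was tested.

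The third pattern is that 139 of 741 listed genes had no row, 19 of 21 B cell markers and 18 of 24 T and NK cell markers among them, against 0 of 30 mitosis genes. The table was possibly computed together with libraries other than these 4, because 934 genes that lay at the floor in all 4 libraries still had rows. That every gene seen only in cKO got no row is argued against by 88 genes raised in 1 cKO library only, with both WT libraries at the floor, in rows shared by at least 20 genes. That such genes got a row less often stays open, since 3461 genes were raised in 1 WT library only, 39.3 times as many, and at the lowest level 2173 against 0; with rows shared by at least 2 genes the counts were 3659 and 416, so the size of this difference depends on the cutoff. No biological explanation was tested.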
